A study of Mus musculus with 6 samples.

How the data were processed

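RNA was measured in 6 libraries of immune cells sorted from the myometrium, the muscular wall of the uterus, of pregnant mice at embryonic day 13.5. Per the labels, the females were 8 to 12 weeks old, were on a C57BL/6 background and had been mated with BALB/cJ males. The control group held 3 libraries from mice with floxed Il18 alleles. The conditional knockout group, written cKO here, held 3 libraries from mice that also carried Sm22a-cre, which deletes floxed Il18 in smooth muscle cells. Per the labels' protocols, the tissue was digested enzymatically, leukocytes were enriched on Lympholyte-M, and cells positive for both CD45 and IL-18R were collected by flow cytometry. RNA extraction, cDNA synthesis and library construction used the SMART-Seq HT PLUS kit, a full-length cDNA method for small numbers of cells.

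The deposited table held raw read counts per gene, as whole numbers, for 55487 genes in the 6 libraries. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0 and the mouse genome build GRCm38. The counting tool, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Every count column belonged to a library of this series. Of the gene identifiers, 55141 (99.4%) were in the GENCODE M21 name table. Coordinates are those of the deposited table, on GRCm38.

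Some limits follow from how the counts were made. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Genes with near-identical copies elsewhere can lose or share reads: Gapdh, which has many processed pseudogenes, was counted at 16.2 CPM in the control libraries, and mt-Co2, which has a nuclear copy, at 19.8 CPM beside 7835 CPM for mt-Co1. Values of such genes, and of the Klra (Ly49) receptor family, are therefore uncertain in level. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

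Library totals lay between 29911176 and 32965030 counts. A gene with 0 counts in a library was taken to be below 3 counts, which is 0.0910 CPM in the largest library and 0.1003 CPM in the smallest. A fold against a group at 0 was computed against 3 counts over the whole group and is a lower bound. These limits cover counting error and not the variation between mice. Levels are in CPM, a gene's count scaled to its library total, and are given as mean ± SD over the 3 libraries of a group.

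Genes were filtered with filterByExpr of edgeR 4.0.16 at its default minimum count of 10, which kept 14057 genes. Normalization used TMM factors, which lay between 0.971 and 1.05. Dispersions were estimated with estimateDisp, which this edgeR release requires before the fit. Differences were tested with edgeR's quasi-likelihood F-test (glmQLFit and glmQLFTest) on all 6 libraries with genotype as the model's term, two-sided, and Benjamini-Hochberg adjustment over all tested genes at 0.05. Log2 fold changes are cKO minus control. The biological coefficient of variation was 0.765, from a common dispersion of 0.585. In R 4.3.3, limma 3.58.1 supplied camera, fry and voom, and DESeq2 1.42.0 its Wald test, with its independent filtering set for an adjusted p of 0.05. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

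The design, the tests, the other settings of the tests, the rule for named genes and 35 gene lists of cell types and pathways were fixed before the data were examined. Tests of explanations in the closing section were written later, after a first look at the gene and list results. Lists with at least 3 tested genes, 34 of the 35, were tested with camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, and adjusted over the lists. Camera with a correlation estimated per list, and fry, which asks whether a list's genes move one way (directional p) or either way (mixed p), were run beside it. The p-values of a list's members were also adjusted over the list alone.

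Named genes were chosen by rule. They were Il18, Il18r1, Il18rap and Tagln whatever their p, and up to 12 genes per direction that passed the threshold with groups that did not overlap. In each list, up to 4 members that passed over all genes were to be named, and in a list called by camera the 3 members with the smallest p. With fewer than 10 genes past the threshold, the 6 genes per direction with the smallest unadjusted p were given as values that did not pass. Other list members are given as examples and were chosen after their values were seen.

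Other settings covered other scalings, other filters on low counts, thinning to the smallest library, leaving out each library in turn, a replicate block, DESeq2, voom with and without quality weights, a robust fit, a threshold of 0.1, removal of mitochondrial genes, other set tests and a prior count of 0.5. One list variant, the natural killer list without Klra genes, and a list of tissue-resident macrophage genes were added after seeing the data.

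The tests were tested on simulated data: counts for the 14057 genes were drawn from the means and library sizes of these libraries, with 200 genes changed per draw in 5 draws. The edgeR test recovered 4.2% of the genes changed 2-fold and 28.8% of those changed 4-fold, with 7 false calls among 173. DESeq2 recovered 21.6% and 52.4%, with 432 false calls among 819. A planted list of 15 genes was shifted by 0.8 on the log2 scale. Camera gave it an unadjusted p under 0.05 in 5 of 5 draws, both at the preset and at the estimated correlation. Of 500 unchanged lists, 4.4% and 0.2% had an unadjusted p under 0.05. Genes were drawn independently of each other, so these shares do not speak to lists whose genes are correlated, such as the NK list with an estimated 0.424. Comparisons of list means between groups used an exact permutation test over the 10 splits of 6 libraries, whose smallest two-sided p is 0.1.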

Results

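The experiment asked how smooth muscle-derived IL-18 shapes the immune cells of the pregnant uterus. IL-18 is a cytokine of the interleukin-1 family whose receptor consists of the chains encoded by Il18r1 and Il18rap. Leukocytes carrying IL-18R were compared between control mice and mice in which Sm22a-cre deletes Il18 in smooth muscle (cKO). Read counts summed to 30828083, 29911176 and 30001301 in control libraries 1, 2 and 3 and to 30922504, 31352327 and 32965030 in cKO libraries 1, 2 and 3. Between 15935 and 16933 genes had at least 1 read per library. Across 9962 genes with a mean of at least 5 CPM, Spearman's rho between libraries was 0.884 to 0.908 within groups and 0.881 to 0.906 between groups. The first principal component held 23.1% of the variance and did not follow genotype: control library 1 scored with cKO libraries 2 and 3, and control libraries 2 and 3 scored with cKO library 1. The second held 20.8%, and its scores did not overlap between genotypes: -1.32, -85.8 and -66.0 in the controls and 105, 32.7 and 15.4 in cKO. Chance separates 3 libraries from 3 on a given component in 10% of cases. Control library 1 scored nearer to cKO library 3 than to the other controls.

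Il18 itself (chromosome 9, 50554827 to 50581840) was read in every library, at 80.6, 56.5 and 49.4 CPM in the controls and 52.3, 44.9 and 34.8 CPM in the cKO libraries. The means were 62.2 ± 16.3 and 44.0 ± 8.78 CPM, and the log2 fold change of -0.55 ± 0.28 (SE) did not pass edgeR's quasi-likelihood test (adjusted p = 0.999). The sort kept leukocytes and the deletion was directed to smooth muscle, so this level does not check the deletion. Tagln, the gene whose promoter drives the Cre, had 2 reads in control library 1, 4 in cKO library 1 and none in the other 4 libraries. The receptor chains were read throughout: Il18r1 at 69.0 ± 22.2 CPM in controls and 58.9 ± 10.1 CPM in cKO, and Il18rap at 88.3 ± 25.2 and 154 ± 26.8 CPM. Every cKO library had more Il18rap than every control library, with a log2 fold change of 0.75 ± 0.26 (SE) that did not pass (adjusted p = 0.999).

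The sorted cells were rich in myeloid transcripts. Lyz2, a lysozyme of macrophages, was at 12461 ± 1641 CPM in controls and 10307 ± 538 CPM in cKO, Cd74, the MHC class II invariant chain, at 11536 ± 1162 and 8821 ± 1286 CPM, and the complement gene C1qb at 3163 ± 263 and 3225 ± 244 CPM. Lymphoid transcripts included those of gamma-delta T cells, with the constant region Trdc between 290 and 1201 CPM over the 6 libraries, and of natural killer (NK) cells, with the cytotoxic protease gene Gzma between 808 and 2608 CPM. Smooth muscle genes were low, with Acta2 at 3.44 ± 1.28 and 0.851 ± 1.47 CPM. The 4 Y-linked genes examined, which male fetal cells would carry, had 0 counts in all 6 libraries, which allows at most 0.1003 CPM in any library.

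NK cell transcripts were more abundant in the cKO libraries. All 15 genes of the NK list had a higher mean in cKO, by 0.72 on the log2 scale on average, and in 11 of them every cKO library lay above every control library. Chance gives non-overlapping groups for 10% of genes, in either direction. The list's genes were correlated (estimated at 0.424), so the 11 are not independent observations. Ncr1, which encodes the activating receptor NKp46, was at 157 ± 34.4 CPM in controls and 296 ± 41.1 CPM in cKO, a log2 fold change of 0.87 ± 0.21 (SE). Klre1, a lectin-like receptor, was at 155 ± 24.2 and 288 ± 36.1 CPM, a log2 fold change of 0.85 ± 0.18 (SE). Klra4, which encodes the receptor Ly49D and shares sequence with other Klra genes, was at 94.5 ± 6.84 and 200 ± 29.2 CPM, a log2 fold change of 1.03 ± 0.18 (SE).

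The NK list rose as a set by camera with the preset correlation (adjusted p = 2.72e-08 over 34 lists). That call was lost with an estimated correlation (adjusted p = 0.708) and in fry's directional test (adjusted p = 0.400). None of its members passed edgeR's test over all genes. When adjusted over the list alone, 9 of the 15 passed, the smallest adjusted p being 0.00910. The mean log2 CPM of the list was 7.21, 6.80 and 7.33 in the control libraries and 7.97, 7.63 and 7.90 in the cKO libraries, with an exact permutation p = 0.1, the smallest this design allows. The groups did not overlap in 7 of the 34 lists, where chance gives 3.4: NK cells, ILC2, smooth muscle, fibroblasts, erythroid cells, growth factors and immediate-early genes. Among the other members, Klrb1c, which encodes the surface antigen NK1.1, was at 89.6 ± 34.5 and 204 ± 48.2 CPM. Gzma was at 1220 ± 358 and 2242 ± 393 CPM, while Cd244a, at 96.6 ± 38.7 and 104 ± 18.4 CPM, differed by less than the spread between libraries.

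**Figure D1:**
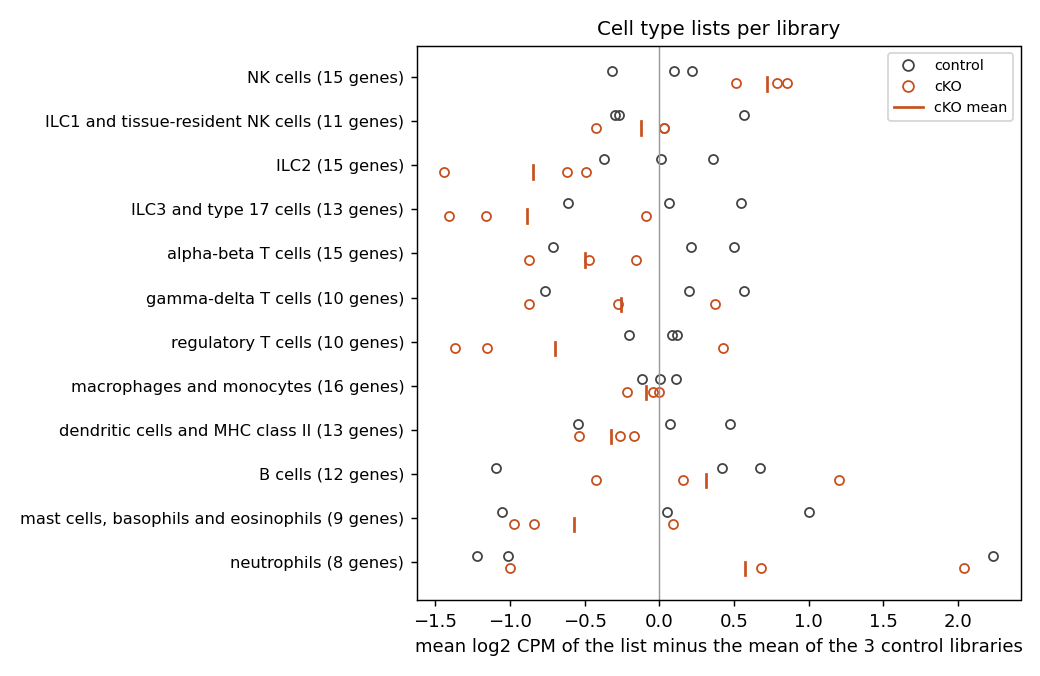
Mean log2 CPM of each cell type list per library (open points), minus the mean of the 3 control libraries; vertical bars mark the cKO mean. The cKO mean of the NK list lay 0.72 above that of the controls with no overlap between groups. The ILC2 list also did not overlap, with a difference of -0.85. The T cell lists overlapped between groups.

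Effector genes of type 1 immunity were not called as a set (16 genes, mean log2 change 0.16, median 0.43, camera adjusted p = 0.312), although 12 of the 16 were higher in cKO. In 4 members every cKO library lay above every control library, and in 1 below. The cytotoxic genes Gzmb, at 381 ± 89.2 CPM in controls and 577 ± 118 CPM in cKO, and Prf1, the gene of perforin, at 97.7 ± 47.3 and 172 ± 21.5 CPM, had higher means in cKO. Ifng, the interferon-gamma gene, was at 45.6 ± 20.8 and 30.1 ± 3.79 CPM, and Csf2, the gene of the growth factor GM-CSF, at 28.7 ± 13.4 and 5.43 ± 4.92 CPM. No member passed edgeR's test over all genes or when adjusted over the list alone. The interferon-gamma response list (16 genes, mean log2 change 0.24, adjusted p = 0.330) and the type I interferon list (16 genes, 0.20, adjusted p = 0.503) also held no call.

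Lists of T cells and of other innate lymphoid cells had lower means in cKO, and none was called by camera. Group 2 innate lymphoid cell (ILC2) genes had a mean log2 change of -0.85 over 15 genes (adjusted p = 0.153), which shrank to -0.32 with a stricter filter (adjusted p = 0.271) and to -0.54 without cKO library 3 (adjusted p = 0.539). Of the 15, 4 were higher and 11 lower in cKO. Every cKO library lay above every control library in 2 members and below in 2. Areg and Il9r passed when adjusted over the list alone (smallest adjusted p = 0.00578). Areg encodes the epidermal growth factor family ligand amphiregulin and was at 76.5 ± 28.0 CPM in controls and 18.4 ± 2.77 CPM in cKO. Il9r, the interleukin-9 receptor gene, was at 5.83 ± 4.77 CPM in controls and had 0 counts in all 3 cKO libraries, at least 187-fold lower. The ILC2 list changed in fry's mixed test (adjusted p = 1.42e-05), which counts movement in either direction and does not compare the list with other genes. The same held for the secreted growth factors (17 genes, mean log2 change -0.60, camera adjusted p = 0.127, fry mixed adjusted p = 0.0298), where Areg passed over the list alone and the mean shrank to -0.30 with the stricter filter (adjusted p = 0.259). Spp1, the osteopontin gene, was at 2844 ± 580 and 1605 ± 476 CPM there.

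T cell lists overlapped between groups. The mean log2 change was -0.50 for alpha-beta T cells (15 genes, adjusted p = 0.0957), -0.26 for gamma-delta T cells (10 genes, adjusted p = 0.330), -0.89 for ILC3 and type 17 cells (13 genes, adjusted p = 0.127) and -0.70 for regulatory T cells (10 genes, adjusted p = 0.0753). Trdc was at 306, 899 and 1201 CPM in the controls and 693, 450 and 290 CPM in cKO, and Il17a at 182, 333 and 565 CPM and 243, 147 and 216 CPM. Mean log2 CPM of the gamma-delta T list was 6.17 in control library 1 and 6.66 and 6.07 in cKO libraries 2 and 3. It was 7.14 and 7.51 in control libraries 2 and 3 and 7.31 in cKO library 1. The alpha-beta T and ILC3 lists split the libraries the same way, as did the first principal component, and the neutrophil list in reverse. The regulatory T list did not. Lower alpha-beta T, gamma-delta T and ILC3 means in cKO cannot be told apart from this split, which crosses genotype. Control library 1 held the fewest T cell transcripts of the controls. Without it, camera called the alpha-beta T (-0.85, adjusted p = 1.16e-04), gamma-delta T (-0.63, adjusted p = 0.00212), ILC3 (-1.18, adjusted p = 0.00664) and ILC2 (-1.02, adjusted p = 0.00834) lists as lower. Without cKO library 1, it called the ILC3 (-1.28, adjusted p = 0.0199) and alpha-beta T (-0.67, adjusted p = 0.0283) lists. Other libraries pulled the opposite way: without control library 3 the changes were -0.24 for alpha-beta T (adjusted p = 0.732) and -0.61 for ILC3 (adjusted p = 0.529), and without cKO library 3 alpha-beta T was at -0.30 (adjusted p = 0.473). The gamma-delta T list turned positive without control library 3 (0.0324) and without cKO library 3 (0.0558). Among regulatory T cell genes, Tnfrsf4, which encodes the costimulatory receptor OX40, passed over the list alone (adjusted p = 0.0192), at 44.6 ± 17.6 CPM in controls and 13.4 ± 1.36 CPM in cKO. DESeq2 called Tnfrsf4 (adjusted p = 9.88e-04) and, in the other direction, Ikzf4 of the same list (adjusted p = 0.0346). Mean Ikzf4 was 0 CPM in controls and 5.50 CPM in cKO. It did not pass the low-count filter, so edgeR did not test it, and not every cKO library reached the filter's minimum count. With a stricter filter that left 8 of its genes, the regulatory T list was called (-1.05, adjusted p = 0.00582). Its change shrank to -0.20 without a filter (adjusted p = 0.222) and to -0.17, -0.15 and -0.30 without control library 1, 2 or 3. The main filter kept 10 of its 11 genes, and Ikzf4 entered without a filter. A left-out library also lowers the number of libraries the filter asks for, so these changes are not all over the same genes. The list of ILC1 and tissue-resident NK cells was not called (11 genes, -0.12, adjusted p = 0.628).

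The macrophage and monocyte list was not called as a whole (16 genes, mean log2 change -0.09, adjusted p = 0.485). Its members lay on both sides, 6 higher and 10 lower in cKO. In 7 of the 16, edgeR's unadjusted p was under 0.05, against 593 of all 14057 tested genes. Cx3cr1, a chemokine receptor of monocytes and macrophages that NK cells also express, was at 219 ± 26.9 CPM in controls and 324 ± 17.4 CPM in cKO. Csf1r, the receptor for macrophage colony-stimulating factor, was at 505 ± 20.1 and 771 ± 193 CPM, while Cd14 was at 1046 ± 126 and 807 ± 19.0 CPM. Of the dendritic cell and MHC class II list (13 genes, -0.32, adjusted p = 0.312), H2-Aa was at 3106 ± 450 and 2325 ± 206 CPM and Cd74 was lower in every cKO library than in every control library. The list's mean was -0.0755 without control library 1, -0.59 without control library 2 and -0.11 with the stricter filter. No member of either list passed edgeR's test over all genes or over the list alone, while DESeq2 called Cx3cr1 (adjusted p = 0.0367). Lists of B cells (12 genes, 0.31, adjusted p = 0.630), of mast cells, basophils and eosinophils (9 genes, -0.57, adjusted p = 0.423) and of neutrophils (8 genes, 0.57, adjusted p = 0.580) held no call. The mast cell list ran from -0.0110 without cKO library 3 to -1.18 without control library 2. Without control library 1, whose neutrophil genes were the highest of the controls, the neutrophil list was called as higher (1.70, adjusted p = 0.0151), but its mean turned negative without control library 2 (-0.18), control library 3 (-0.0888) or cKO library 3 (-0.15).

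Genes of fibroblasts and decidual stroma fell as a set (9 genes, mean log2 change -2.48, camera adjusted p = 0.00710), with levels that varied widely between libraries. That call was lost with an estimated correlation (adjusted p = 0.708), in fry's directional test (adjusted p = 0.400), without control library 2 (-1.95, adjusted p = 0.0555) and with a stricter filter that left 3 genes (-1.73, adjusted p = 0.179). No member passed edgeR's test over all genes or when adjusted over the list alone (smallest adjusted p = 0.130). The collagen genes were high in control library 2: Col1a1 was at 0.941, 101 and 3.13 CPM in the controls and 2.52, 0 and 0.182 CPM in cKO, Col1a2 at 4.12, 91.4 and 6.87 CPM and 0, 1.44 and 0 CPM, and Col3a1 had 148, 908 and 115 reads and 16, 47 and 99 reads. Prl8a2, a decidual prolactin-family gene, was at 376 CPM in control library 3 and at most 68.6 CPM in the other 5 libraries. Of the other non-leukocyte lists, smooth muscle (4 genes, -1.57, adjusted p = 0.602), erythroid cells (4 genes, -1.46, adjusted p = 0.376), endothelium (3 genes, 0.45, adjusted p = 0.485) and epithelium and trophoblast (4 genes, 0.18, adjusted p = 0.793) were not called. The endothelial list was called without cKO library 2, where 5 of its genes were tested (1.67, adjusted p = 0.0282), and was at 1.72 without control library 1 (adjusted p = 0.178) and 0.10 without cKO library 1 (adjusted p = 0.789). The erythroid mean shrank to -0.60 without control library 1, and the smooth muscle mean to -0.83 without cKO library 1.

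Signalling and housekeeping lists were not called by camera. IL-18 receptor and signalling genes had a mean log2 change of 0.13 (13 genes, adjusted p = 0.423) and NF-kB response genes of -0.09 (14 genes, adjusted p = 0.485). The immediate-early genes, which also respond to tissue dissociation, had a mean log2 change of -0.20 (17 genes, adjusted p = 0.277), with the nuclear receptor gene Nr4a1 at 292 ± 27.1 CPM in controls and 232 ± 11.2 CPM in cKO. The remaining lists had adjusted p between 0.427 for glycolysis and hypoxia (16 genes, -0.36) and 0.949 for mitochondrially encoded transcripts (13 genes, 0.01). They were cell cycle (21 genes, -0.08), oxidative phosphorylation (20 genes, -0.06), cytosolic ribosomal proteins (20 genes, 0.04), common gamma chain signalling (14 genes, 0.12), inhibitory receptors (13 genes, 0.08), glucocorticoid and progesterone response (11 genes, -0.07), p53 response (11 genes, -0.19), and trafficking and tissue residency (17 genes, -0.02). For the trafficking list camera's direction was up while the mean and median were negative, and for the mitochondrial list the median was -0.02 with a positive mean. No member of these lists passed when adjusted over the list alone.

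Gene by gene, edgeR called 0 of 14057 transcripts (smallest adjusted p = 0.708), with 593 at an unadjusted p under 0.05 where chance gives 703. Groups did not overlap for 1475 genes, 10.5% of those tested, against 10% by chance. Limma voom also called 0 genes, with 794 under an unadjusted 0.05, while DESeq2 called 207 of the 14414 left by its filtering, of which 109 were higher and 98 lower in cKO. Over the 23079 genes to which DESeq2 gave a p, 1374 were under an unadjusted 0.05 where chance gives 1154. In simulated counts with the spread of these libraries, 432 of 819 DESeq2 calls were false, summed over 5 draws. That share depends on how many genes were changed in the simulation, so it does not give the share of false calls among the 207. In the same simulated counts edgeR recovered 4.2% of genes changed 2-fold and 28.8% of those changed 4-fold, so changes of this size can have gone uncalled.

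The genes with the smallest unadjusted p are given here as values that did not pass edgeR's test, each with an adjusted p = 0.708. Among those higher in cKO, the zinc finger gene Zfp952 (chromosome 17, 32993129 to 33005457) was at 6.61 ± 1.47 CPM in controls and 34.6 ± 5.32 CPM in cKO, a log2 fold change of 2.34 ± 0.35 (SE). Slc35a3, which encodes a Golgi transporter of UDP-N-acetylglucosamine, was at 30.9 ± 3.44 and 72.2 ± 8.73 CPM. Klra13-ps, a Klra pseudogene that can share reads with its paralogs, was at 123 ± 12.4 and 251 ± 36.3 CPM, and Klra4 was again among them. Gk5, a gene of the glycerol kinase family, and Zfp94 had 0 counts in the controls and were at 5.13 ± 1.97 and 3.18 ± 0.579 CPM in cKO, at least 157-fold and 95.9-fold higher.

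Among those lower in cKO, F13a1, the A subunit of coagulation factor XIII (chromosome 13, 36867178 to 37050244), was at 170 ± 22.2 CPM in controls and 67.3 ± 15.6 CPM in cKO, a log2 fold change of -1.39 ± 0.21 (SE). Cd209f, a C-type lectin gene of the DC-SIGN family (chromosome 8, 4102787 to 4105835), was at 23.0, 12.2 and 7.33 CPM in the controls and had 0 counts in all cKO libraries, at least 452-fold lower. Cbr2, a carbonyl reductase gene, was at 70.2 ± 25.1 and 19.7 ± 4.22 CPM, and the C-type lectin gene Clec4a3 at 369 ± 22.5 and 239 ± 15.4 CPM. Areg (chromosome 5, 91139599 to 91148432) had a log2 fold change of -2.11 ± 0.34 (SE). Dgkg, a diacylglycerol kinase gene, was at 5.71 ± 2.26 CPM in controls and had 0 counts in cKO, at least 181-fold lower.

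**Figure D2:**
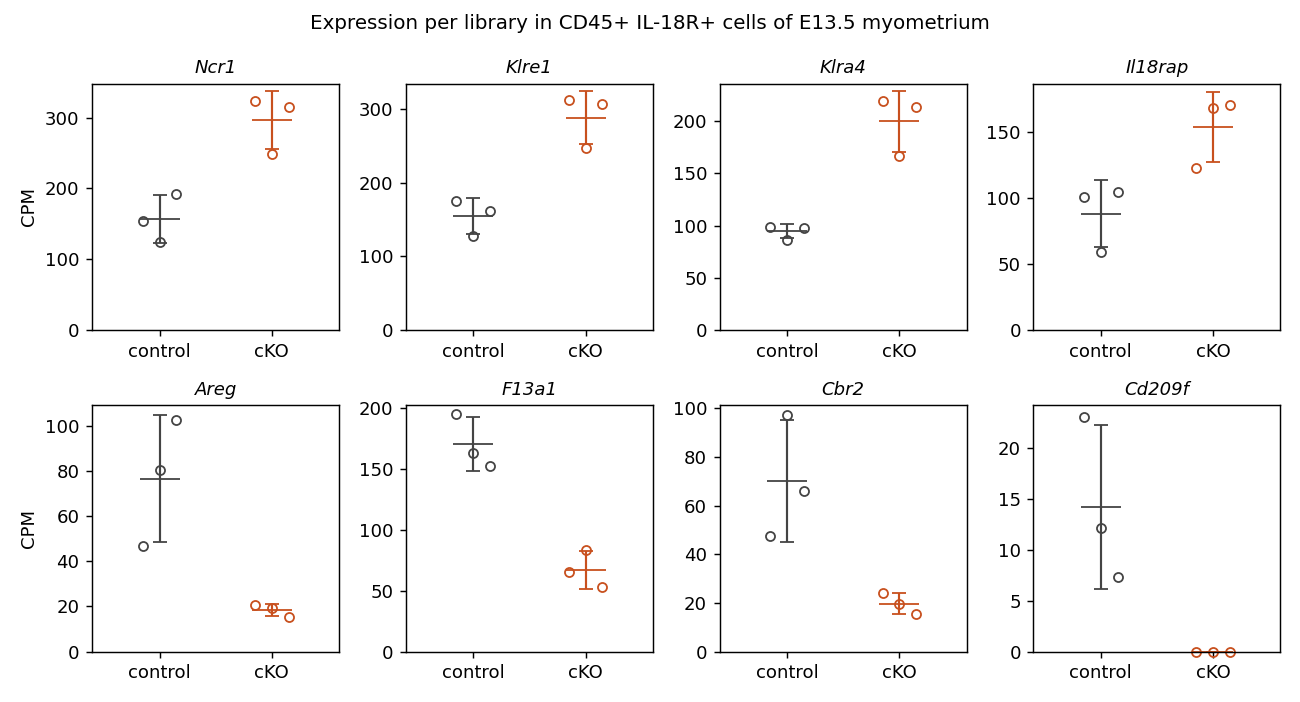
CPM of 8 genes in each library (open points), with the mean and SD of the 3 libraries of each group (bars); axes start at 0. In each panel the groups do not overlap: Ncr1 ran from 124 to 192 CPM in controls and from 249 to 324 CPM in cKO, Areg from 46.9 to 102 CPM and from 15.3 to 20.6 CPM, and no panel's gene passed edgeR's test over all genes.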

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

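With edgeR, the count of 0 changed genes was the same under other scalings, filters, thinning, each left-out library, a robust fit, a threshold of 0.1 and removal of mitochondrial genes, and with voom. DESeq2 called 207, among them 14 of the named genes, in the same direction. No tested named gene changed sign under any alternative. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.07, -0.01 and -0.01, no library matched its own number best, and the replicate block gave 0 genes and 2 lists. The NK list stayed called under 14 settings, with mean log2 changes from 0.57 to 0.84 and adjusted p from 2.15e-09 to 1.62e-04. With an estimated correlation and with fry's directional test 0 lists were called. Both use the correlation between genes seen in the libraries, 0.424 for the NK list. Leaving out 1 library in turn gave 1 to 7 called lists against 2: 7 without control library 1, 1 without control library 2 and 4 without cKO library 1. The cause was not tested.

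The low-count filter was applied anew when libraries or counts changed, so a list's genes could differ between settings. The fibroblast list, for example, held 9 genes in the main run and 11 without control library 1. Lists that were not called reversed their mean log2 change as follows, and the cause was not tested. Leaving out a library gave -0.631 to 0.0558 for gamma-delta T cells, -0.10 to 0.31 for inhibitory receptors, -0.32 to 0.0787 for cell cycle, -0.18 to 1.70 for neutrophils, -0.26 to 0.17 for ILC1, -0.36 to 0.62 for B cells, -0.31 to 0.20 for glucocorticoid response, -0.17 to 0.82 for epithelium, -0.13 to 0.10 for trafficking and -0.0574 to 0.14 for mitochondrial transcripts. A stricter filter (5 CPM in 3 libraries) gave -0.0839 for inhibitory receptors, -0.52 for epithelium and -0.0210 for mitochondrial transcripts. No filter gave -0.15 for epithelium, and library size alone gave 0.0324 for trafficking. Other means that were not called kept their sign but moved by more than 1.5 times when a library was left out. Their ranges were 0.0509 to 0.34 for type 1 effectors, 0.12 to 0.43 for interferon-gamma, 0.0704 to 0.41 for type I interferon, -0.44 to -0.0399 for p53 and -0.19 to -0.0289 for NF-kB. Common gamma chain, IL-18 signalling, glycolysis, immediate-early, oxidative phosphorylation, ribosomal and macrophage means also did so. Of the other list results, 461 kept their direction and side of the threshold, 9 became calls and 6 lost one. Depth was nearly equal, and thinning every library to the smallest changed no count of calls. Scaling moved the median of all genes by at most 0.0510 on the log2 scale.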

Other observations

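Every explanation below was written down after a first look at the gene and list results, and the tests chosen after their own result was seen were the count of edgeR calls over other splits, those of a lower share of T cells and innate lymphoid cells, of Klra paralogs and of chromosome 6 for the NK list, and that of macrophages of every kind. Homing and adhesion receptors of the trafficking list lay on both sides. Sell, the gene of L-selectin, was at 92.8 ± 16.6 CPM in controls and 167 ± 29.8 CPM in cKO, the integrin gene Itga4 at 93.5 ± 6.97 and 145 ± 15.4 CPM, and the chemokine receptor gene Ccr5 at 250 ± 37.7 and 368 ± 11.8 CPM. Cd69, a marker of activation and tissue retention, was at 758 ± 219 and 498 ± 152 CPM. Hdc, the histidine decarboxylase gene of mast cells and basophils, was at 80.1 ± 7.01 and 40.3 ± 16.3 CPM. Of macrophage genes outside the fixed lists, the chemokine gene Ccl8 was at 119 ± 109 CPM in controls and 20.3 ± 8.73 CPM in cKO, and the folate receptor gene Folr2 at 5.57 ± 4.32 and 0.530 ± 0.278 CPM. None of these passed edgeR's test over all genes. DESeq2 called Itga4 (adjusted p = 0.00969), Ccl8 (adjusted p = 0.0130), Folr2 (adjusted p = 0.0140) and Sell (adjusted p = 0.0477).

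NK cell genes were higher in cKO as a set by camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.708) and in fry's directional test (adjusted p = 0.400). A lower share of T cells and innate lymphoid cells alone would have raised markers of macrophages, dendritic cells, B cells and mast cells alike. Their mean log2 change was -0.14 over 50 genes, and the NK list lay 0.86 above it (SE 0.15 over genes). Reads shared among Klra paralogs would have raised only that family. The 11 members outside it had a mean log2 change of 0.66 (SE 0.11 over genes). A strain difference at the NK gene complex would have raised only members on chromosome 6. The 6 members on other chromosomes had 0.64 (SE 0.16 over genes). In these libraries the rise was therefore not confined to the Klra family or to chromosome 6. The errors treat correlated genes as independent and leave out the spread between libraries, so the tests do not rule out any of these explanations. Of the 10 splits of the libraries, the real one gave the list the smallest camera p, 8.00e-10, against 1.71e-05 for the next, and 1 in 10 splits is too few to judge chance. A larger share of NK cells among IL-18R-positive cells and higher transcript levels per NK cell both stay open as hypotheses, since the sort on IL-18R and pooled RNA leave them unseparated.

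Genes of tissue-resident macrophages may be lower in cKO, a hypothesis prompted by Cd209f, F13a1 and Cbr2. A list of 18 such genes, written after those were seen, that left out the prompting genes and shared none with the other lists held 16 tested genes, 15 of them lower, with a mean log2 change of -1.20 (SE 0.31 over genes), a median of -0.67 and a camera p = 4.58e-05 that became p = 0.139 with an estimated correlation. The rule written first asked only for a camera p under 0.05 and was met; the need for the estimated correlation was added after the uneven levels were seen, and by that stricter rule the pattern cannot be judged. Fewer macrophages of every kind would have lowered the fixed macrophage and monocyte list by about as much. That list lay 1.11 above the added list (SE 0.32 over genes). The error treats correlated genes as independent and leaves out the spread between libraries, so the test does not rule this explanation out. Library means of the added list gave an exact permutation p = 0.4 between groups. The difference was uneven, with list means of 4.96, 4.47 and 2.18 log2 CPM in controls and 2.33, 3.15 and 2.54 in cKO. The change was -0.64 over 16 genes without control library 1. Without control library 3 it was -2.26, over the 18 genes that then passed the filter, so the genes differed as well as the libraries. In 3 of 10 splits, the real one counted, the camera p was as small (lowest other 1.00e-06), and 10 splits are too few to judge chance.

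DESeq2 called 207 genes where edgeR called 0. Genes with reads in 1 group alone were a candidate source: 89 of the calls, 43.0%, had a group mean under 1 CPM, against 16.4% of the 14414 genes left by its filtering, and in 62 a group was at 0, a share between the bounds set for and against this explanation, which stays open. Among the 10 splits, 2, the real one counted, gave as many DESeq2 calls. The split of control library 1 with cKO libraries 2 and 3 against the rest gave 519. It divides the libraries as the first principal component of the same counts does, so it is not separate evidence for that component. Genotype came second, just above the next split with 196. Trim59, for example, was at 94.8 CPM in controls and 44.0 CPM in cKO (DESeq2 adjusted p = 3.94e-05).

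Over the 10 splits of the 6 libraries, edgeR called 0 genes in all 10. Camera called 2 lists in the real split and up to 7 in the others, with as many or more in 5 of the 10, the real one counted; 10 splits are too few for a share under 0.05.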
